A study of Drosophila melanogaster with 12 samples.

How the data were processed

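RNA was measured in 8 libraries and p53-bound chromatin in 4, each the only library of its group, from adult heads and from embryos of the yw strain and of a p53 mutant strain. Per the labels, polyA RNA was made into paired-end stranded libraries. Chromatin was fixed for 10 min in 1% formaldehyde, sheared to 200 to 300 bp and precipitated with 2 µg of p53 antibody. Per the submitters' processing notes, RNA reads were handled with cutadapt, TopHat2, Picard, SAMtools and Cuffdiff, and chromatin reads with cutadapt, Bowtie2, Picard, SAMtools and MACS2, on the dm6 build. Versions, the gene annotation and whether replicates were pooled before Cuffdiff or MACS2 are not given in the sources used here.

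The deposited RNA tables, 1 per tissue, hold FPKM per gene and group, made by the authors with Cuffdiff per the file headers, together with 6 columns of log2 fold changes computed by the authors after adding 1 FPKM. The authors' deposited log2 columns differed from log2(FPKM + 1) differences of the same tables by at most 0.0167. Cuffdiff scales each library by a single factor, so a difference in RNA content per cell is not seen, and FPKM divides fragments among overlapping genes and near-identical copies. The 2 tissues were processed in separate tables, and every difference was taken within a table. The deposited peak lists give for each peak a fold (ratio) of wild-type over p53 mutant chromatin, a −log10 p-value, a −log10 q-value and the offset of the summit from the peak start, made by the authors with MACS2. The peak lists compare wild type with the mutant as background, so a locus that differs in copy number or sequence between the strains can give a peak. Folds were used within a list only. The strain tags inside the authors' peak names differ from the mutant name in the labels.

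Differences were taken as log2(FPKM + 1), with a pseudocount of 1 FPKM, among genes at 1 FPKM or more in at least 1 of the 4 groups of a tissue, and counted at 2-fold. With 1 library per group no test across libraries was made. The p53-dependent response was the wild-type minus the mutant difference, counted at 2-fold where the wild-type response passed 2-fold in the same direction. Overlaps of gene counts are given beside the product expected of independent lists. Library depth was read from FPKM: the common step of FPKM times length, in genes with 1 transcript of 800 to 3000 bp, is the value of 1 fragment. The length was reduced by 150 bp, picked after the data were seen from 6 values tried. It gave the clearest steps in 4 of the 8 libraries, those of embryos, while head libraries had slightly clearer steps at 200 or 250 bp. Over the 6 values the depth estimates ranged from 9.26 to 15.5 M fragments in heads and from 16.9 to 24.4 M in embryos, and counting intervals depend on this choice. The simulation below used the same 150 bp and so does not test it. The estimates were 10.7, 12.9, 13.6 and 11.8 M fragments for head wild-type control, wild-type irradiated, mutant control and mutant irradiated, and 19.0, 21.1, 21.7 and 22.7 M for the same groups of embryos. Fragment estimates, made for transcripts of 300 bp or more, gave exact binomial intervals of ratios, which cover counting error only. Tested on simulated data with 200 changed genes, 90% to 98% of 4-fold or larger changes were recovered at these depths. Unchanged genes past 2-fold numbered 25 to 38 per head comparison and 1 to 5 per embryo comparison.

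Before the data were examined, 26 gene lists with 503 symbols were fixed, of which 26 symbols were not found in the tables, 15 of them the mitochondrial transcripts. The text gives results of p53 targets, apoptosis, DNA repair, JNK response, gut, immune effectors, heat shock, Turandot and JAK-STAT, glutathione and redox, fat body and yolk proteins, muscle, maternal transcripts, early zygotic genes, piRNA pathway, later patterning and neurogenesis, phototransduction, cell cycle, neurons, glia, the reproductive tract, sex composition, circadian clock, starvation and autophagy. Not every median in a tail is printed. The median of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries. Of 120 list medians per tissue, 42 in heads and 43 in embryos lay in either tail (the outer 5%) of the random lists, where 6 would by chance. Named genes were chosen by a rule fixed at the same time: p53 first, the 8 largest rises and falls of each comparison among genes at 5 FPKM or more in at least 1 group, every p53 target, up to 4 members per list past 2-fold, and the 10 largest p53-dependent rises and falls. For peaks the rule took the 10 highest folds per tissue, up to 15 shared peaks and every peak within 5 kb of a start of a p53 target. Outside the rule, and chosen after the values were seen, are roX1, Akh, LysD, TpnC4, maternal genes beyond the first 4, the genes recurring across tissues, and responding bound genes that the rule did not name.

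Peaks were compared with bedtools 2.31.1 at an overlap of 1 bp and beside 1000 random placements on the same chromosomes. Starts, exons and introns came from the Ensembl release 115 annotation of the same assembly, and gene identifiers of the tables were matched to it for 99.8% and 99.7% of expressed genes in heads and embryos. A gene was bound if a summit lay within 1 kb of a start. Shares have exact binomial intervals at the 95% level, and 2 by 2 tables were tested by two-sided Fisher's exact tests. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

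Alternatives fixed beforehand were a pseudocount of 0.1 FPKM, no filter or a filter of 5 FPKM, centring of each comparison, summits within 100 bp or reciprocal overlap for shared peaks, the peaks of each list with the smaller q-values, starts within 200 bp or 5 kb, and a 1.5-fold threshold. After the data were seen, 12 alternatives were added, which leave out small RNA genes, digestive enzyme families, runs of adjacent peaks or p53, merge near peaks, or place random peaks at other starts. Also decided after the data were seen were the class of small RNA genes, the families of digestive enzymes, the length limit on fragment estimates, and a correction of the step estimate after it returned too small a step on simulated data. The simulation results given are those of the corrected estimate. A search for the p53 motif was not made, since genome sequence was not used here, and the authors' significance call was not used, since the tables as used here carry no q-value.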

Results

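The transcript response to ionizing radiation and the genomic binding of p53 were measured in adult heads and in early embryos of the fly Drosophila melanogaster. p53 is a transcription factor that acts after DNA damage, and in fly embryos it is known to switch on a group of cell death genes. The labels set an embryo, with dividing cells, beside the adult head, which holds mostly neurons and glia that no longer divide. RNA came from a wild-type strain (yw) and from a p53 mutant strain, each mock treated or given 40 Gy. Adults were 1 to 2 weeks old, and head RNA was taken after 3 h of recovery. Embryos were treated at an age of 3 to 4 h and sampled 1.5 h later. Chromatin of both strains and both tissues was precipitated with a p53 antibody, and the labels give no radiation treatment for it. The 12 samples were 8 RNA libraries and 4 chromatin libraries, with 1 library per group, so no difference below has a replicate check.

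Depth, read from the steps between low FPKM values, came to 10.7 to 13.6 M fragments per head library and 19.0 to 22.7 M per embryo library. A gene was counted as changed at a 2-fold difference or more on the log2(FPKM + 1) scale, which understates the change of low genes. Counted genes reached 1 FPKM in at least 1 of the 4 groups of a tissue, which left 10672 genes in heads and 10654 in embryos. Counting intervals of a ratio are at the 95% level and cover counting error only.

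The p53 transcript itself, from 3R:23049657-23054082, was measured first. In wild-type heads p53 stood at 11.7 FPKM without and 13.3 FPKM with radiation, against 0.532 and 0.549 FPKM in mutant heads. In wild-type embryos p53 rose from 25.9 to 54.5 FPKM after radiation, a log2 difference of 1.04, and in mutant embryos it stood at 0.700 and 0.340 FPKM. The levels matched the strain labels in each of the 8 RNA libraries.

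The first comparison asked which transcripts responded to radiation in wild-type embryos. Cell death genes of the 3L cluster were among those that rose. The transcript of skl (sickle), an inhibitor of the caspase inhibitor Diap1, rose from 18.8 to 174 FPKM, a log2 difference of 3.14 with a counting interval of 8.39 to 10.2 for the ratio. The related genes rpr (reaper) and W (hid) rose by 2.54 and 1.47. Corp (companion of reaper) rose by 2.21, and egr (eiger), the fly tumour necrosis factor, rose by 1.15. Xrp1, a leucine zipper transcription factor of the DNA damage response, rose from 29.2 to 171 FPKM, a difference of 2.51.

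DNA repair genes moved with them. Irbp and Ku80, which encode the Ku heterodimer of end joining, rose by 1.54 and 1.27, mus205, the catalytic subunit of DNA polymerase zeta, rose by 1.41, and the DNA ligase gene lig3 rose by 1.15. Of the 12 genes on a list of p53 targets, 9 rose and the list median was 1.44, above all of 10000 random lists matched on expression. The others, mre11, RnrL and WRNexo, differed by 0.74, 0.72 and 0.11. The apoptosis list had a median of 0.26 with 4 of 15 members higher, the DNA repair list 0.20 with 4 of 42 higher, and the JNK response list 0.26 with 2 of 12 higher, namely rpr and egr. These 3 medians lay above more than 99.9% of random lists. Later patterning and neurogenesis genes had a median of -0.16 and early zygotic genes a median of -0.13, both near the low end of random lists, with no member past 2-fold.

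**Figure D1:**
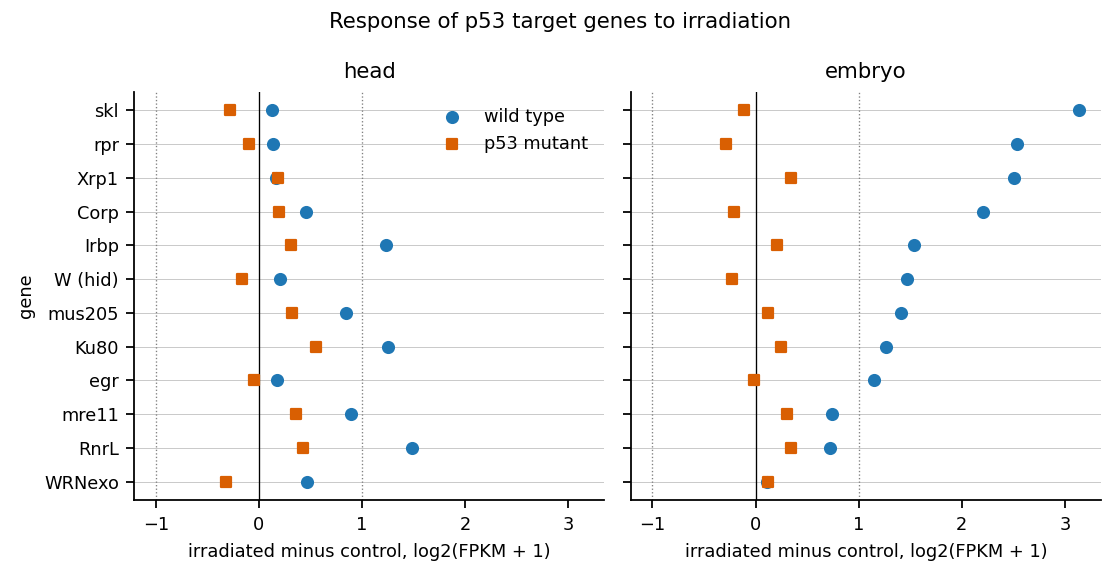
Response of 12 p53 target genes to radiation in heads (left) and embryos (right), as the irradiated minus control difference of log2(FPKM + 1) on the horizontal axis. Circles are wild type and squares the p53 mutant, 1 library per group, and dotted lines mark 2-fold; in embryos 9 of the 12 wild-type circles lie past 2-fold and no mutant square does.

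Genes outside these lists also changed in wild-type embryos. Rab3-GEF, an exchange factor for the synaptic vesicle GTPase Rab3, rose from 1.27 to 25.0 FPKM, a log2 difference of 3.52, and CG34266 was listed at 0 in the control and at 12.0 FPKM after radiation. Transcripts of digestive proteases were also higher. Jon99Fi went from 0.0600 to 19.9 FPKM, Jon25Bi from 0.750 to 21.8 FPKM, and 11 of the 17 expressed members of the gut list rose, with a list median of 1.60. The salivary glue genes Sgs7 and Sgs8, which are known from late larvae, fell by 3.75 and 3.19, and Sgs5 fell by 3.39. Hsp70Bb, a heat shock chaperone gene, fell by 1.98, and Hsp70Ba and Hsp70Bbb fell by 1.41 and 1.28. In all, 141 genes were higher and 95 lower. Small RNA genes, which polyA libraries sample poorly, made up 27 of the rises and 41 of the falls, and without them 114 were higher and 54 lower. The protease and Hsp70 genes have near-identical copies, between which the authors' counting could divide fragments.

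In mutant embryos none of the 12 p53 targets changed with radiation. The differences of skl, rpr, Xrp1 and W were -0.12, -0.28, 0.34 and -0.23, and the list median was 0.12. The gut list again had a median of 1.22, with 10 of its 17 members higher, among them Jon25Bii by 2.11, Jon99Fi by 1.95 and Jon25Bi by 1.79. Of the glue genes among the largest falls, Sgs7 fell from 86.5 to 0.740 FPKM and Sgs3 from 7.54 FPKM to a listing at 0. The heat shock list had a median of -0.19, and Hsp70Bb fell by 1.60. Immune effectors had a median of 0.46 with 2 of 11 members higher, IM3 by 1.74 and PGRP-SC2 by 1.03. Later patterning, early zygotic and muscle genes had medians of -0.19, -0.12 and -0.11, each below more than 99.9% of random lists, and DNA repair and redox genes medians of 0.15 and 0.18, above more than 99.9%, with no member of the 5 lists past 2-fold. In all, 109 genes were higher and 101 lower, or 74 and 57 without small RNA genes. Of the genes past 2-fold in the 2 genotypes, 30 were higher in both, 32 lower in both and 17 higher in one and lower in the other, against 1.44, 0.901 and 2.31 for independent lists.

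The p53-dependent part of the response was taken as the wild-type minus the mutant difference. Rab3-GEF at 3.64, skl at 3.26, rpr at 2.82 and Corp at 2.42 were among the largest p53-dependent rises of the embryo once small RNA genes were left out, with CG34266 at 3.68. CG43346 at -3.19 led the falls. Of the 12 p53 targets, 9 passed 2-fold in this measure and their list median was 1.31. The gut list had a median of 0.62 with 7 of 17 members past 2-fold, while the mutant stood above wild type by a list median of 0.99 without and 0.42 with radiation. In all, 93 genes were higher and 49 lower, of which 22 and 28 were small RNA genes.

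The same question was asked of wild-type heads. The p53 target RnrL, the large subunit of ribonucleotide reductase, rose from 2.63 to 9.16 FPKM, a log2 difference of 1.48 with a counting interval of 2.68 to 4.63 for the ratio. Ku80 rose by 1.26 and Irbp by 1.23. The cell death genes did not pass 2-fold in heads, with differences of 0.13 for rpr, 0.13 for skl, 0.21 for W and 0.18 for egr. Xrp1 was already at 407 FPKM in the control and differed by 0.17. The p53 target list had 3 of 11 expressed members higher and a median of 0.45, above all random lists, and the DNA repair list had a median of 0.22 with the same 3 genes of 40 higher. That the target response differed between head and embryo was not tested, since each tissue has 1 library per group.

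Digestive enzyme transcripts rose in irradiated wild-type heads. Jon65Aiv went from 0.651 to 71.7 FPKM, a log2 difference of 5.46, Jon65Aiii rose by 4.50 and betaTry by 4.05, and epsilonTry was listed at 0 in the control and at 13.3 FPKM after radiation. These genes encode proteases that digest food in the midgut, and 11 of 13 expressed members of the gut list rose, with a list median of 1.97. Of 20 list members found, these 13 reached 1 FPKM in at least 1 head group. For several members, among them alphaTry, epsilonTry, Jon25Bi, Jon25Bii, Jon99Ci and Jon99Cii, that group was the irradiated wild type alone. The share and the median therefore partly follow from the filter. The largest rise was in CG14645, from 1.59 to 368 FPKM. TpnC4, a troponin C of the flight muscle, rose from 0.465 to 5.34 FPKM, as the only 1 of 16 expressed muscle genes past 2-fold, and the muscle list had a median of 0.09. Akh, the adipokinetic hormone of the corpora cardiaca, rose from 1.16 to 6.22 FPKM, and the reproductive tract list had a median of -0.10 with none of 11 past 2-fold. Of 24 immune effectors, 4 were lower. IM2 fell by 1.73, AttA by 1.52, Mtk by 1.14 and CecA2 by 1.10, IM23 and CG18107, from outside the list, were listed at 0 after radiation, and the list had a median of -0.25, below all random lists. The fat body and yolk protein list, with a median of -0.19, lay low as well, with none of its 10 members past 2-fold. Lists of neuron, glia, phototransduction and cell cycle genes had medians of -0.05, -0.03, -0.07 and 0.09 with no member past 2-fold. In all, 162 genes were higher and 52 lower, and 21 of the rises were in digestive enzyme families. In simulated libraries of this depth, counting error alone put 38 unchanged genes past 2-fold.

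In mutant heads the gut list had a median of 0.03 with none of its 13 members past 2-fold, and none of the 11 expressed p53 targets changed, with a list median of 0.20 that lay above 99.7% of random lists. Gut list members such as epsilonTry, at 0.494 and 0.297 FPKM in mutant heads, lay near the floor there. Ku80 differed by 0.55, RnrL by 0.43 and Irbp by 0.32. Diedel, a secreted immune modulator, rose by 1.66 and the metallothionein MtnD by 1.70. CecB fell by 1.89, AttD by 1.05 and CecC by 1.03, as 3 of 24 immune effectors, and that list had a median of -0.23. Muscle, neuron and phototransduction genes had medians of -0.24, -0.17 and -0.13, below all random lists, with no member past 2-fold. The circadian clock, starvation and autophagy lists had medians of 0.13, 0.11 and 0.06, above 99.7%, 98.9% and 97.8% of random lists, again with no member past 2-fold. The reproductive tract list had a median of 0.58, with 4 of 11 expressed members higher and SP (sex peptide) lower. SP, and Mst57Db and Acp95EF from outside the list, which are made in the male accessory gland, stood at 4.90, 26.9 and 7.86 FPKM in the mutant control and were listed at 0 in the other 3 head libraries. Of the 4, Vm26Aa and Vm26Ab, which encode eggshell proteins, rose by 1.76 and 1.68 in the irradiated mutant. In all, 68 genes were higher and 78 lower, and 5 rises and 5 falls were shared with wild-type heads, against 1.03 and 0.380 for independent lists. A further 10 genes were past 2-fold in opposite directions in the 2 genotypes, against 1.52.

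As p53-dependent rises, heads had 138 genes, and 34 genes were lower. CG14645 at 6.76, CG34212 at 6.30, CG16826 at 5.11 and Jon65Aiv at 5.03 were among the largest, and 20 of the 138 were in digestive enzyme families. RnrL, at 1.05, was the only one of 11 expressed p53 targets past 2-fold, followed by Irbp at 0.92 and Ku80 at 0.70. Irbp went from 9.43 to 23.5 FPKM in wild type and from 13.6 to 17.1 FPKM in the mutant. Ku80 went from 5.18 to 13.8 FPKM in wild type and from 9.81 to 14.9 FPKM in the mutant. Both started higher in the mutant, and irradiated mutant heads held no less Ku80 than irradiated wild-type heads. The gut list had a median of 2.15 in this measure and the p53 targets a median of 0.41. Muscle genes had a median of 0.34, with TpnC4 past 2-fold.

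Of 9242 genes expressed in both tissues, 22 rose in wild-type heads and in wild-type embryos, against 0.875 for independent lists. Irbp and Ku80 were the only p53 targets among them, and 12 were digestive enzyme genes, including alphaTry, betaTry, epsilonTry, Jon65Aiv and the lysozyme LysD. Without the digestive families and the gut list, 10 genes rose in both. The families were picked by gene symbol, so related genes named otherwise could remain among the 10. CG13323, CG3819, CG7953, CG4363 and CR44713 among them had a profile like that of the proteases in heads. They stood at 12.6, 8.20, 5.6, 2.7 and 1.8 FPKM in irradiated wild-type heads and below 1 FPKM in the other head libraries. CG18180 was also highest there, at 13.7 FPKM against 1.53 to 3.64 FPKM in the others. A single gene, CR44268, fell in both tissues. MtnB, a copper-binding metallothionein, went from 17.9 to 5.30 FPKM in heads and from a listing at 0 to 5.02 FPKM in embryos.

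**Figure D2:**
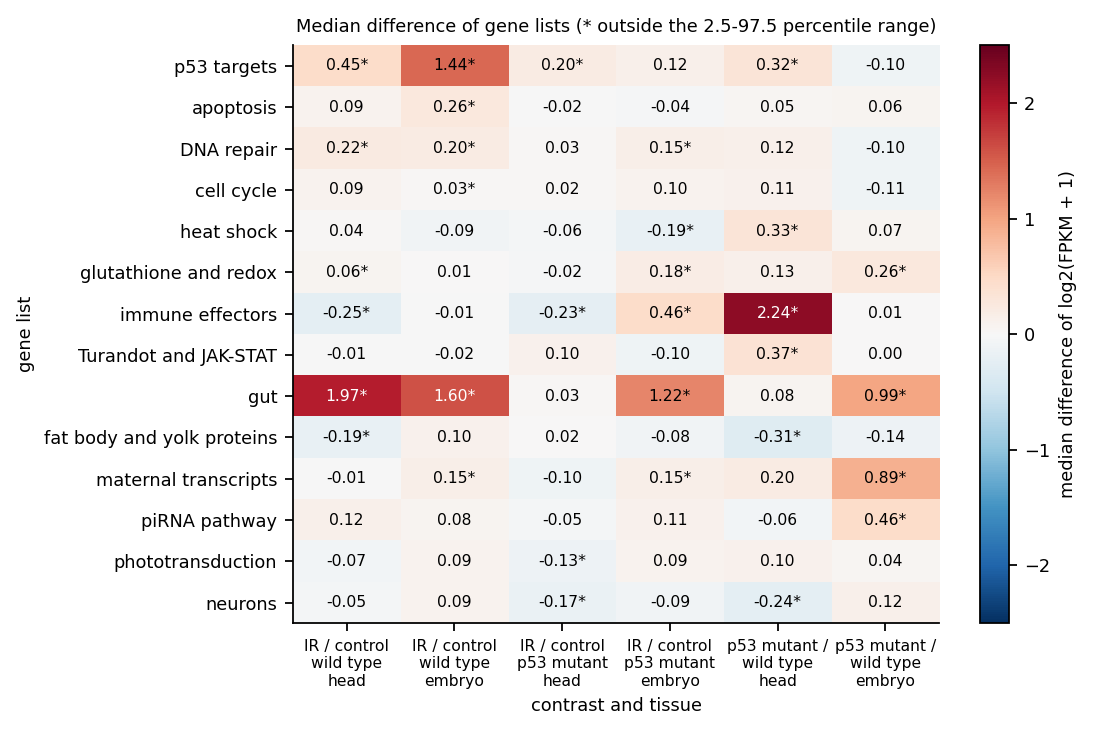
Median difference of log2(FPKM + 1) for 14 gene lists (vertical axis) in the response to radiation in wild type and in the p53 mutant and in the mutant against wild-type control, for each tissue (horizontal axis). Colour and number give the median, and an asterisk marks medians in either tail of matched random lists; the gut list stands at 1.97, 1.60 and 1.22 in irradiated wild-type heads, wild-type embryos and mutant embryos, and the immune effectors at 2.24 in mutant heads.

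The strains were then compared without radiation. Mutant heads held far more transcripts of the humoral immune response. IM23 stood at 650 FPKM against 9.07 in wild type, CecA2 at 699 against 13.6 and Mtk at 535 against 15.2, and 16 of 24 immune effectors were higher, with a list median of 2.24. Of the stress-induced Turandot genes, TotM was higher by 5.66, TotC by 3.07 and TotA by 2.02. The Turandot and JAK-STAT list had a median of 0.37 with 5 of 11 members higher, and the heat shock list 0.33 with 3 of 14 higher. The glutathione and redox list, with 3 of 27 higher, had a median of 0.13, within the range of random lists. Glutathione transferase transcripts GstE8, GstE1 and GstE7 were higher by 1.96, 1.59 and 1.43, and the small heat shock genes Hsp67Bc, Hsp22 and Hsp26 by 1.93, 1.25 and 1.16. Tektin-C, which encodes a protein of the sperm tail, stood at 69.0 against 0.880 FPKM, and tobi, an alpha-glucosidase regulated by insulin and adipokinetic hormone, at 37.9 against 0.643 FPKM.

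Other transcripts were lower in mutant heads. The larval serum protein gene Lsp1beta fell from 500 to 2.07 FPKM, a difference of -7.35, and Lsp2 fell by 1.86. The male-specific X chromosome RNA roX2 stood at 3.06 against 69.6 FPKM and roX1, of the same dosage compensation complex, at 119 against 165 FPKM. Of the rhodopsins of the R8 photoreceptors, Rh6 was lower by a difference of -2.56 and Rh5 higher by 1.23. The repair gene phr, a photolyase, was lower by a difference of -1.17, whereas XRCC1 was higher by 1.16. The pigment gene w stood at 7.86 against 1.02 FPKM, and the yw strain is white-eyed. Without radiation none of the 11 expressed p53 targets passed 2-fold, and their list median was 0.32. The neuron, glia, fat body and yolk protein, and later patterning lists had medians of -0.24, -0.30, -0.31 and -0.36, and the sex composition list, with roX2 and Obp99b past 2-fold lower, a median of -0.47. These 5 lay below more than 99% of random lists, and muscle genes, with a median of 0.25, lay above 99.0%. In irradiated heads the neuron, glia, fat body and yolk protein, and sex composition medians were -0.33, -0.31, -0.28 and -0.34. In all, 462 genes were higher and 348 lower. Among irradiated heads 404 were higher and 460 lower, and 279 and 234 were shared with the unirradiated comparison, against 17.5 and 15 for independent lists. The strains may differ at loci other than p53, and the labels give no shared background.

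Mutant embryos held more maternal transcripts than wild-type embryos. The phosphatase gene twe rose by 1.45, the receptor gene tor by 1.41, and bcd, smg, exu, swa, vas and piwi by 1.04 to 1.07, so that 8 of 17 maternal transcripts were higher, with a list median of 0.89. AGO3, of the piRNA pathway, stood at 26.8 against 11.1 FPKM, and that list had a median of 0.46. The small heat shock genes Hsp27, Hsp26 and Hsp23 were higher by 1.95, 1.38 and 1.16, and Parp, the poly(ADP-ribose) polymerase gene, by 1.25. The protease gene alphaTry stood at 25.5 against 0.240 FPKM, and 8 of 17 gut list members were higher. Besides p53, the cytochrome P450 gene Cyp4p2 and kek1, a regulator of EGF receptor signalling, were lower, by differences of -4.02 and -3.50. Later patterning and neurogenesis genes had a median of -0.21 with none of 31 past 2-fold. With 1 library per group, genotype cannot be told from strain or from another sample difference, such as embryo age within the collection window. In all, 526 genes were higher and 260 lower. Among irradiated embryos 685 were higher and 325 lower, and 388 and 157 were shared with the unirradiated comparison, against 33.8 and 7.93 for independent lists. The p53 targets had a median of -1.47 there, with 9 of 12 lower, led by rpr at -3.04 and skl at -2.92, and a median of -0.10 without radiation. The sex composition, fat body and yolk protein, and DNA repair lists had medians of -0.48, -0.55 and -0.25 among irradiated embryos, with 1 of 6, none of 8 and 4 of 42 members lower, and 2 of the 42 higher.

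Strain differences recurred across tissues. Of genes expressed in both, 75 were higher and 46 lower in the unirradiated mutant of both tissues, against 10.7 and 3.59 for independent lists. Tektin-C, mthl8 and XRCC1 were among the genes higher in both, and CG32581, Cyp4p2 and roX2 among those lower in both. In embryos Tektin-C differed by 4.06 and roX2 by -2.90.

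The authors' peak lists hold regions where the wild-type chromatin exceeded the p53 mutant chromatin, and the fold of each peak is the authors'. The head list held 392 peaks and the embryo list 135. In heads the highest fold, 14.5, lay at X:6192340-6193260, between genes and near a start of Ca-alpha1T, which encodes a T-type calcium channel. Peaks in an intron of Ptp61F (13.8), in an intron of Mnt (13.5) and in an intron of Xrp1 at 3R:18923721-18924643 (11.7) followed within the first 7. In embryos the highest fold, 7.35, lay in the same intron of Xrp1, at 3R:18923945-18924590, followed by a peak between genes near Tom (5.65), which lies in a run of adjacent peaks, and a peak in the 5' UTR of egr at 2R:10078203-10078601 (5.04) among the first 5. The intron of p53 itself carried a peak in both tissues, at 3R:23053047-23053644 in heads and 3R:23053164-23053505 in embryos, and this locus differs between the strains. Runs of at least 3 peaks within 5 kb held 59 head and 52 embryo peaks.

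Of the 135 embryo peaks, 73 (54.1%) overlapped a head peak by at least 1 bp, and 75 of the 392 head peaks (19.1%) overlapped an embryo peak. Randomly placed peaks gave a mean of 0.299 and at most 3 overlaps, and the one-sided permutation p of 0.001 is the smallest that 1000 placements can give. Shared peaks included those at Xrp1, egr, W, Corp, p53, Rtnl1, REPTOR, crp and Tlk. Summits lay within 1 kb of a transcription start for 263 head peaks (67.1%, exact interval 62.2 to 71.7%) and for 59 embryo peaks (43.7%, 35.2 to 52.5%), against 23.8% and 23.7% of randomly placed peaks. The difference between the tissues had a two-sided exact Fisher p of 2.19e-06. Among shared peaks the share near a start was 58.7% in heads and 60.3% in embryos. Among the others it was 69.1% in heads and 24.2% in embryos, where it stood near the random share. Shared peaks overlap between the tissues, so their like shares largely follow from how they were defined. That the tissue difference fell among the other peaks is therefore not a separate result. On the X chromosome lay 108 head peaks (27.6%, 23.2 to 32.3%) and 17 embryo peaks (12.6%, 7.51 to 19.4%), with an exact Fisher p of 0.000389. Of shared peaks 16.0% in heads and 16.4% in embryos lay on X, and of the others 30.3% and 8.06%. Both p values are across peaks of 1 list per tissue, which are not replicates. Counted by reciprocal overlap the shared embryo peaks came to 42 of 135 (31.1%), among the peaks of each list with the smaller q-values to 35 of 67 (52.2%), and without peaks in runs to 45 of 83 (54.2%).

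Among the p53 targets, W (hid), egr, Corp and Xrp1 carried a peak within 5 kb of a start in both tissues. In heads these lay at 3L:18185573-18185900, 127 bp upstream of the start of W, at 2R:10078199-10078593, 2 bp upstream of egr, at X:8271487-8271854 in an intron of CG1632, 256 bp upstream of Corp, and at the Xrp1 intron. Their folds in the head list were 4.11, 4.32, 8.17 and 11.7. The embryo list held a further peak at 3L:18187508-18187786, 2012 bp upstream of W, and a peak at 3L:18403082-18403517 (fold 4.59), 4870 bp upstream of rpr and between genes. The head list held no peak within 5 kb of rpr or skl. A deposited list holds called peaks only, so weaker binding at rpr in heads is not excluded.

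**Figure D3:**
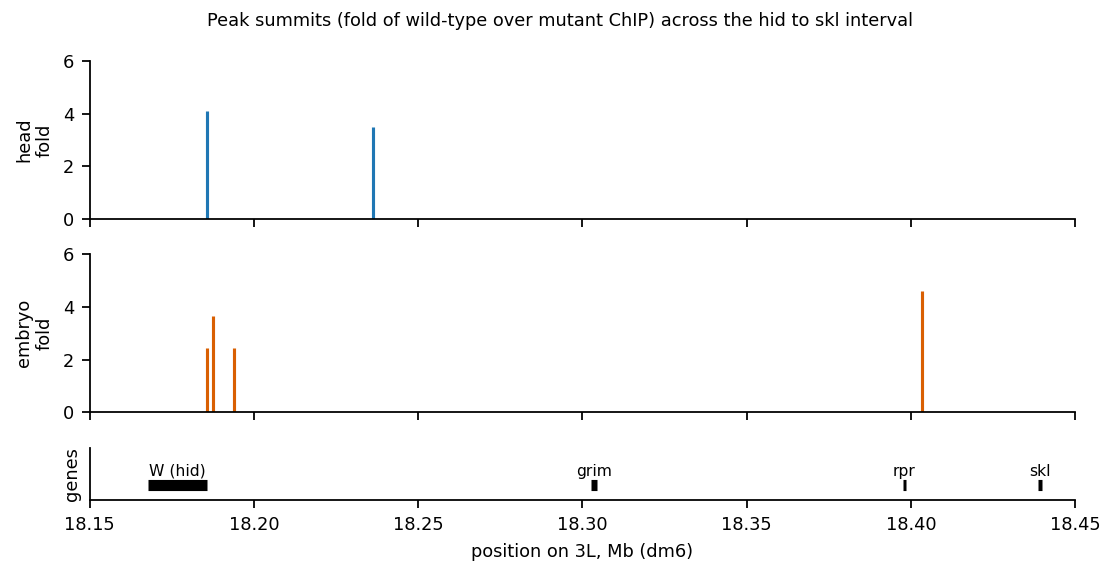
Peak summits in heads (top) and embryos (middle) and cell death genes (bottom) from 18.15 to 18.45 Mb of 3L, dm6 build. The height of each line is the authors' fold of wild-type over mutant chromatin within that list; both tissues have a peak beside W (hid), and only the embryo list has one beside rpr.

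Binding was then joined with expression within each tissue. In embryos 63 expressed genes had a summit within 1 kb of a start. Of these, 9 changed in wild type after radiation (14.3%, against 2.14% of other genes, odds ratio 7.61, two-sided exact Fisher p 9.21e-06 across genes, which are not replicates). Rab3-GEF, Xrp1, Corp, CR44381, W, egr, Rtnl1 and p53 rose, by 3.52, 2.51, 2.21, 1.64, 1.47, 1.15, 1.08 and 1.04, and CG16713 fell by 1.04. Without p53, whose locus differs between the strains, 8 of 62 genes changed (12.9%, Fisher p 6.02e-05). CR44381 went from 2.17 to 8.91 FPKM in wild type and already stood at 9.68 FPKM in the mutant control. Rtnl1, which shapes the endoplasmic reticulum, went from 578 to 1220 FPKM. In mutant embryos 0 of the 63 genes passed 2-fold, against 1.98% of other genes, with a Fisher p of 0.638, so about 1 gene would be expected.

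In heads 299 expressed genes had a summit within 1 kb of a start, and 2 of them changed after radiation (0.669%, against 2.04% of other genes, Fisher p 0.137), CG15456 by 1.22 and CR45135 by -1.57. In mutant heads 0 of the 299 passed 2-fold, against 1.41% of other genes, with a Fisher p of 0.0369. For the wild-type head response with starts within 5 kb, the share was 1.70% against 2.02%, with a Fisher p of 0.761. Of 52 genes bound and expressed in both tissues, 0 changed in heads and 8 in embryos. Exact tests of these shares across genes do not test a difference between the tissues, since genes are not replicates and each response rests on 1 irradiated and 1 control library, with 3 h of recovery in heads and 1.5 h in embryos. The expressed bound genes had a median of 33.4 FPKM against 21.5 FPKM for other genes in heads and 37.5 against 19.5 FPKM in embryos.

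**Figure D4:**
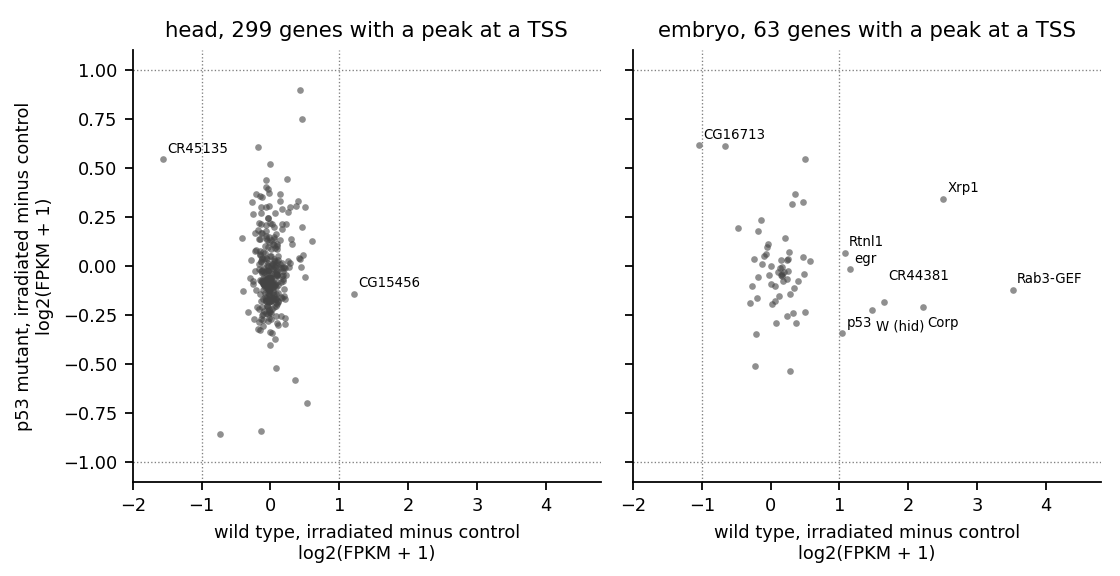
Response to radiation of genes with a p53 peak summit within 1 kb of a start, in heads (left, 299 genes) and embryos (right, 63 genes). Each point is 1 gene, with the wild-type difference of log2(FPKM + 1) on the horizontal axis and the mutant difference on the vertical axis, and dotted lines mark 2-fold; 9 embryo genes and 2 head genes pass it in wild type and none does in the mutant.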

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

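Of the tests in this part, only the one of gut epithelium genes had its gene list and prediction written before the values were seen; all others were chosen after the pattern was noticed.

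Digestive enzyme transcripts were higher in irradiated wild-type heads and in irradiated embryos of both genotypes. Counting error of low transcripts is argued against in heads, where 11 of 13 expressed members of the gut list had a counting interval of the ratio above 1. The list was fixed before the values were seen. The 13, of 20 members found, were those at 1 FPKM in any head group. For several, among them alphaTry, epsilonTry, Jon25Bi, Jon25Bii, Jon99Ci and Jon99Cii, this was the irradiated wild type alone. The share of the 13 therefore partly follows from the filter. Of all 20 members found, at least 11 still had such an interval. Dependence on p53 as the sole source in embryos is argued against by the irradiated mutant embryos, in which 10 of 17 gut list members were also past 2-fold higher, although for 7 of 17 the rise was past 2-fold larger with p53, with a list median of 0.62 for the difference, from a mutant control whose list median was already 0.99 above wild type. Gut RNA carried into the irradiated wild-type head library may contribute, and this stays open. Of 6 expressed gut epithelium genes outside the enzyme families, 0 were past 2-fold higher. However, mesh had a counting interval of 1.25 to 2.82 for the ratio. The near-floor mex1 went from 0.335 to 1.22 FPKM, a log2 difference of 0.73 with an interval of 0.772 to 35.5. PGRP-SC2 and Ssk already stood at 59.2 and 23.8 FPKM in the control, so a small carried amount need not double them. TpnC4 of flight muscle and Akh of the corpora cardiaca were higher in the same library, beside a muscle list median of 0.09. These 2 genes were picked for their rise. With 1 library per group, radiation cannot be told from a difference between the 2 samples, and no biological explanation was tested.

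Head peaks lay on the X chromosome more often than embryo peaks (exact Fisher p 0.000389). Within the head list, 30.3% of peaks not shared with embryos and 16.0% of shared peaks lay on X. The like share of 16.4% for shared peaks in embryos is fixed, since overlapping peaks lie on the same chromosome. Gene content of X is argued against, since 16.4% of expressed genes lie there, below the interval of 23.2 to 32.3% for head peaks. Weak calls added by an unequal X dose of the 2 chromatin samples would raise the X share among weaker peaks. The X share was 32.1% among the stronger and 23.0% among the weaker peaks of the head list (exact Fisher p 0.0543). This direction is opposite to that explanation, but the test did not decide it. The sexes in each chromatin sample are not given in the sources used here, and no biological explanation was tested.

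Runs of adjacent peaks numbered 16 in heads and 11 in embryos, of which 4 were found in both. A copy number or sequence difference between the strains is a candidate explanation: 42 of 59 head peaks in runs, against 154 of 333 others, lay below the median fold of the list (exact Fisher p 0.000606). Loss of the transcripts under the runs in the mutant points the same way, since 7 of 12 genes under runs of both tissues, among them ana2, Sec31 and IntS12, had a counting interval of mutant over wild type below 1 in both controls, against 12.3% of 9169 genes. These 12 genes are neighbours at 2R:8893748-8900626, 3R:15131609-15140523 and 3R:26858094-26864489. They are not independent observations, and neither are adjacent peaks of a run, so the weight of these shares is limited. Neither test separates a strain difference from p53 binding over a broad region, which stays open.

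The remaining results are differences between the tissues. MtnB differed by -1.58 in irradiated wild-type heads and by 2.59 in wild-type embryos, and by -1.51 and 2.02 in the mutant, and the differences were not tested. Genes at 5 FPKM or more past 2-fold in opposite directions in the 2 tissues numbered 10 for the mutant against wild type without radiation and 24 with it, not tested. Immune effectors had medians of -0.23 and 0.46 in irradiated mutant heads and embryos, not tested. Muscle genes had medians of 0.0877 and -0.20 in irradiated wild-type heads and embryos, not tested. The share of peaks at promoters differed between head and embryo with an exact Fisher p of 2.19e-06, and the responding share of bound genes with 3.64e-06. These p values are across peaks and genes, which are not replicates, and do not test the tissues, since each rests on 1 library per group and recovery was 3 h in heads and 1.5 h in embryos.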

How the results depend on the processing

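The alternatives that leave out genes or peaks in runs were chosen after seeing the data. Of 86 values under an alternative, 64 stayed within their limits, 21 moved and 1 became stronger. Some of the 64 could not move. Without a filter no gene below 1 FPKM in all groups can pass 2-fold between 2 libraries. This fixed every value without a filter, including the p53-dependent counts, which also need a wild-type response past 2-fold. Other random placements leave the count of shared peaks as it is. The balance of higher and lower genes was not stable in the mutant responses. In embryos 109 higher and 101 lower became 198 and 229 with a pseudocount of 0.1 FPKM, 65 and 71 with a filter of 5 FPKM, 99 and 110 after centring and 93 and 100 without digestive genes, and in heads 68 and 78 became 31 and 30 with the filter and 74 and 72 after centring. With a pseudocount of 0.1 FPKM the genes past 2-fold came to 480, 369 and 378 for wild-type, mutant and p53-dependent responses in heads, to 486, 427 and 303 in embryos, to 1274 and 1536 for mutant against wild-type embryos without and with radiation, and to 41 for rises shared by the tissues. With a filter of 5 FPKM, which tests fewer genes, they came to 92, 61 and 78 in heads, 569 for irradiated mutant against wild-type heads, 136 for the mutant embryo response and 11 shared rises. Without small RNA genes the mutant embryo response came to 131 and the p53-dependent one to 92, and without digestive genes the shared rises to 10. Shared peaks came to 42 of 135 (31.1%) by reciprocal overlap, whereas 35 of 67 (52.2%) among smaller q-values and 45 of 83 (54.2%) without runs come from shorter lists, with shares close to 54.1%. Bound head genes past a 1.5-fold threshold came to 1.34%, against 4.92% of others, with a Fisher p of 0.0022 that does not allow for the higher expression of bound genes, and at 2-fold within 5 kb the p was 0.761. Where no construction is named, the cause was not tested. Of 405 named values past 2-fold, 403 stayed past it after centring; a smaller pseudocount can only enlarge a difference between 2 libraries. The counts of changed genes thus depend on how low transcripts are treated, and head libraries are the shallower. No paired analysis was possible because each group has 1 library. The motif alternatives and those with the authors' significance call were not run.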

Other observations

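The genes here were chosen after their values were seen. Of the strain differences in heads, Obp99b, an odorant-binding protein gene, stood at 42.7 FPKM in the mutant and 204 FPKM in wild type, Ilp2, an insulin-like peptide gene, at 56.8 and 118 FPKM, and the amylase gene Amy-d at 8.49 and 48.9 FPKM. Rh5 lies under a run of head peaks. CG13794 stood at 39.3 FPKM in mutant and 6.51 FPKM in wild-type heads, and at 1.27 FPKM in mutant and 22.6 FPKM in wild-type embryos.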
